A study of Mus musculus with 12 samples.

How the data were processed

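RNA was profiled from 12 pooled litters of C57Bl/6J mouse embryos, 6 from dams given vehicle and 6 from dams given cyclopamine. Per the labels' protocols, total RNA was treated with DNase, converted to cDNA with primers that avoid ribosomal RNA, amplified by in vitro transcription, carried through another cycle of cDNA synthesis and end-labelled with biotin, with 1 array per pooled litter. The labels call the litters of a group biological replicates, and a pooled litter is the unit of replication throughout. Pooling averages over the embryos of a litter, so that differences between embryos, among them the share of males, enter as differences between litters. Amplification can compress or distort differences of dim transcripts, and nothing in the values allows this to be measured.

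The deposited table of the authors holds log2 signals, 1 per row and array. The log2 scale was read from the values, which ran from 1.67 to 14.19 with array medians that differed by at most 0.08. Per the submitters' processing notes, GCOS and the Transcriptome Analysis Console 2.0 were used, without the step each was used for. The summarisation, the normalization and the genome build are not given in the sources used here, and the values were used as deposited. Such signals compress real ratios near background, so folds of dim genes can understate the difference in transcript number, and no detection calls were used here. Single probes were not analysed here. No pair of arrays shared more than 30 identical values among 41345 rows, so no array was treated as a repeat of another. The number of columns of other samples was 0.

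Rows were named with the platform annotation given for this work. It named 1 gene symbol for 23521 of 41345 rows and several for 1814, and 16010 rows were unnamed here. Rows with several symbols or none were left out. Of the 23521 rows, 23328 had an Entrez Gene identifier in a RefSeq gene table of the mouse, and all of these had the same symbol in both. For the 1082 genes with more than 1 row, the row with the highest mean over all arrays was used, which left 22180 genes. No filter on dim genes was applied. No genomic positions are printed, since the build was not known.

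The comparison, cyclopamine minus vehicle, was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without covariates, and p values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. A count at 1.5-fold or more was taken from the same fit. Standard errors are the moderated ones of limma. Adjusted p values of genes are from limma unless another test is named.

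In all, 33 gene lists for the tissue, the pathway and other cell types were fixed before the data were examined, with 599 members, of which 551 were measured. The 32 lists with at least 5 measured members were tested, two-sided, with camera of limma at a preset correlation of 0.01, and again with a correlation estimated per list. Camera compares a list with all other genes. Of the 32 lists 12 passed, 5 higher and 7 lower, and 6 passed with an estimated correlation, namely Hedgehog targets, ventral forebrain and forkhead mesenchyme (lower) and placode, surface ectoderm and migratory crest (higher). Fry, which asks whether the genes of a list move on balance in one direction or at all but compares them with no other genes, called 8 lists by direction and 21 regardless of direction. The mean of a list per litter was compared with an exact two-sided permutation test over the 462 distinct splits of the 12 litters, whose smallest p is 0.00216, and it called 9 lists after adjustment. Intervals are 95% intervals of the difference between group means over litters, with a pooled variance. Lists overlap: 12 of the 19 Hedgehog targets also stand in another list. The sex-linked list, with 4 measured genes, was not tested. The median, the mean or the camera direction differed in sign for the retinoic acid, dorsal forebrain, orofacial cleft, fibroblast growth factor and paraxial mesoderm lists, none of which passed.

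The genes named were set by a rule before the data were examined: the 12 largest increases and the 12 largest decreases among genes past the threshold; Gli1, Ptch1, Hhip, Shh, Smo, Foxf2, Foxf1, Foxd1, Foxd2, Nkx2-1 and Ccnd1 whatever their values, with a further item that is not reported here; and, for each list, up to 4 members with the largest changes past the threshold or, where 0 passed, the 2 with the largest. This gave 77 genes, 29 of them past the threshold. Other list members are named as examples, chosen after their values were seen.

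The fit was tested on simulated data with the number of genes, the litters and the spread of the real ones, in which 50 genes per size were changed. At 6 litters against 6, 46% of genes changed 1.23-fold were recovered, 76% at 1.41-fold, 98% at 1.62-fold and 98% at 2-fold. Of 169 calls 10 were false (5.92%). With no gene changed 1 was called, and of 30 unchanged lists 0 were called. The simulation drew its noise independently for each gene, without the correlation between genes that the real arrays have. It also made 169 calls against 49 in the real data, and more calls ease the adjusted threshold. The shares of recovered genes and of false calls therefore do not carry over to the real data, least of all for lists. Real recovery may be lower. In the simulation, at this number of arrays, changes of about 1.23-fold were missed more often than found.

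Alternatives set before the data were examined were quantile normalization, centring of each array on its median, leaving out the dimmest rows, testing every row, averaging the rows of a gene, fits without the trend, with robust variance or with no moderation, array weights, the replicate number as a block, an adjusted p of 0.01, and each litter left out in turn. Added after the data were seen were array cluster as a block or each cluster alone, a score of Y-linked genes as a covariate, leaving out both litters numbered 1, and the exact permutation test of list means. Array clusters were set by the sign of the leading principal component after group means were removed. Other splits of the arrays were refitted for 100 of the 462 splits, drawn with a fixed seed. In the 99 splits other than the real one, camera at the preset correlation called 5 lists in the median, so its calls are given with those of the estimated correlation.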

Results

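Cyclopamine, a plant steroidal alkaloid that inhibits Smoothened, the membrane protein that passes on the Hedgehog signal, was given to pregnant C57Bl/6J mice while the embryonic face was forming. Pumps placed under the skin of the dams at GD8.25 (gestational day) released 120 mg/kg of the drug per day, or its vehicle alone, until tissue was taken at GD9.25. From embryos with 20 to 24 somite pairs, the frontonasal process, which gives rise to the upper midface, was collected with the ventral forebrain beneath it, and the pieces of a litter were pooled. Each pooled litter gave 1 RNA sample and 1 array, so that 6 vehicle and 6 cyclopamine litters were compared. The comparison asks which transcripts of this tissue respond when Hedgehog signalling is inhibited over this window.

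Values were log2 signals of 41345 rows of the array, from which 22180 genes were tested. Array medians lay between 6.56 and 6.64, and the Spearman correlation of all rows between any 2 arrays lay between 0.968 and 0.993. The number of arrays limits the precision of every value given here. After group means were removed, the leading component of variation held 33.4% of the variance and parted the arrays into 7 (3 vehicle, 4 cyclopamine) and 5 (3 vehicle, 2 cyclopamine). Because this structure is not the treatment, differences within the larger and the smaller of these array clusters are given beside the pooled ones for the genes of main interest.

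Genes that Hedgehog signalling activates were lower in cyclopamine-exposed tissue. Gli1, the transcription factor whose own transcription reports pathway activity (Entrez Gene 14632), fell 1.65-fold, from 8.80 ± 0.12 to 8.07 ± 0.21 (log2, mean ± SD, n = 6 litters each). Ptch1, the Hedgehog receptor (Entrez Gene 19206), fell 1.51-fold, from 11.47 ± 0.11 to 10.87 ± 0.07, and Hhip, which binds and sequesters Hedgehog ligands, fell 1.55-fold, from 6.92 ± 0.19 to 6.29 ± 0.13. Each of these genes was lower in all 6 cyclopamine litters than in any vehicle litter. Their log2 changes were -0.72 (SE 0.09, limma adjusted p = 0.00199), -0.59 (SE 0.05, adjusted p = 1.88e-05) and -0.63 (SE 0.09, adjusted p = 0.00727). Within the larger and the smaller array cluster, Gli1 differed by -0.76 and -0.72, Ptch1 by -0.64 and -0.54, and Hhip by -0.63 and -0.69.

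Of 19 measured Hedgehog target genes in the list fixed beforehand, 9 fell, 0 rose and 10 did not pass the test over all genes. Adjusted over the list alone, 13 fell and 0 rose. The mean change of the list over litters was -0.46 (95% interval -0.55 to -0.37), and it was -0.48 and -0.46 within the larger and the smaller array cluster. Camera placed the list below the other genes with adjusted p = 4.47e-29, and with adjusted p = 0.00164 with an estimated correlation. The exact permutation test of the list mean gave adjusted p = 0.0139. Members that did not pass included Foxc2 at -0.43 (adjusted p = 0.0527), Foxa2 at -0.42 (adjusted p = 0.116) and the cell-cycle gene Ccnd1 at -0.07 (SE 0.03, adjusted p = 0.680).

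The list fixed for ligands, co-receptors and transducers of the signal, which leaves out the target genes Ptch1 and Hhip, did not pass. Among its 19 measured genes 0 rose and 0 fell over all genes, and the list mean was 0.03 (95% interval -0.02 to 0.08, camera adjusted p = 0.112). Without vehicle litter 6 the mean was 0.04 and the list passed camera at the preset correlation as higher (adjusted p = 0.00823). Shh itself was at 6.13 ± 0.19 in vehicle and 5.92 ± 0.18 in cyclopamine litters (log2, n = 6 each), a difference of -0.21 (SE 0.10, adjusted p = 0.714). Smo, which encodes the target of the drug, was at 11.43 ± 0.07 and 11.48 ± 0.09 (difference 0.05, SE 0.04, adjusted p = 0.900). Gas1, a Hedgehog co-receptor, had the largest difference of the list, 0.22 (SE 0.05, adjusted p = 0.117). Adjusted over the list alone, 1 of the 19 genes rose and 0 fell.

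Transcription factors of the ventral forebrain were also strongly reduced, though Nkx2-9, Nkx2-2 and Nkx2-1 among them also belong to the Hedgehog target list. Nkx2-9, a homeobox gene expressed next to sources of Hedgehog ligand, showed the largest change of any gene past the test: it fell 3.01-fold, from 9.26 ± 0.12 to 7.67 ± 0.32 (log2, n = 6 each; change -1.59, SE 0.12, adjusted p = 6.45e-06). Olig2, a basic helix-loop-helix factor of ventral progenitors, fell 2.09-fold, Nkx2-2 fell 2.06-fold and Nkx2-1, which specifies the hypothalamus and the medial ganglionic eminence, fell 1.73-fold. Their log2 changes were -1.07 (SE 0.16, adjusted p = 0.00875), -1.04 (SE 0.13, adjusted p = 0.00330) and -0.79 (SE 0.09, adjusted p = 0.00163). Within the larger and the smaller array cluster the changes were -1.51 and -1.74 for Nkx2-9, -1.09 and -1.11 for Olig2, -1.19 and -0.88 for Nkx2-2, and -0.87 and -0.68 for Nkx2-1.

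Of 23 measured ventral forebrain genes, 4 fell, 0 rose and 19 did not pass. Adjusted over the list alone, 7 fell and 1 rose. The list mean was -0.33 (95% interval -0.43 to -0.22, camera adjusted p = 2.25e-14, adjusted p = 0.00976 with an estimated correlation). Because 4 of the 23 genes were also in the Hedgehog target list, the other 19 were tested apart, a test chosen after the values were seen. Their mean was -0.19 (95% interval -0.30 to -0.08, exact permutation p = 0.00216, the smallest that the 462 splits allow). Early eye-field and hypothalamic genes were not uniformly lower: Six3 was at 0.05 (adjusted p = 0.960), Six6 at 0.01 (adjusted p = 0.978) and Rax at 0.20 (adjusted p = 0.282). In 23 dorsal forebrain genes, with Neurog2 at -0.25 (adjusted p = 0.358) and Rspo3 at -0.21 (adjusted p = 0.819; -0.11 without cyclopamine litter 5), 0 rose and 0 fell over all genes and 2 rose and 1 fell adjusted over the list alone. Their mean was -0.01 (95% interval -0.08 to 0.06).

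Of the forkhead genes listed for the facial mesenchyme, Foxf2, Foxf1 and Foxd1 fell. The pieces also held ventral forebrain, so the tissue in which they fell was not resolved. Foxf2 (Entrez Gene 14238), a forkhead factor needed for palate development, fell 1.71-fold, from 7.68 ± 0.28 to 6.91 ± 0.15 (log2, n = 6 each; change -0.77, SE 0.11, adjusted p = 0.00847). Foxf1 fell 1.61-fold (change -0.68, SE 0.11, adjusted p = 0.0158) and Foxd1 fell 1.42-fold (change -0.50, SE 0.10, adjusted p = 0.0454). When 1 litter at a time was left out, the Foxd1 call was lost in 10 of 12 fits (adjusted p up to 0.124) and the Foxf1 call in 1. Within the larger and the smaller array cluster the changes were -0.78 and -0.84 for Foxf2, -0.81 and -0.51 for Foxf1, and -0.51 and -0.51 for Foxd1. Foxd2 was at 8.54 ± 0.10 and 8.55 ± 0.13 (difference 0.01, SE 0.06, adjusted p = 0.986).

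Of 12 measured forkhead genes 3 fell, 0 rose and 9 did not pass. Adjusted over the list alone, 5 fell and 0 rose. The list mean was -0.22 (95% interval -0.33 to -0.12, camera adjusted p = 2.21e-06, adjusted p = 0.0420 with an estimated correlation). It held 6 genes of the Hedgehog target list, and the other 6 had a mean of -0.00 (95% interval -0.11 to 0.10, exact permutation p = 0.952). General markers of the cranial crest mesenchyme showed no shift past the test. Of 22 such genes, among them Twist1 at -0.02, Prrx1 at 0.05, Six2 at -0.33 (adjusted p = 0.417) and Twist2 at -0.28 (adjusted p = 0.367), 0 rose and 0 fell, also adjusted over the list alone, with a list mean of 0.00 (95% interval -0.08 to 0.08, camera adjusted p = 0.537).

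**Figure D1:**
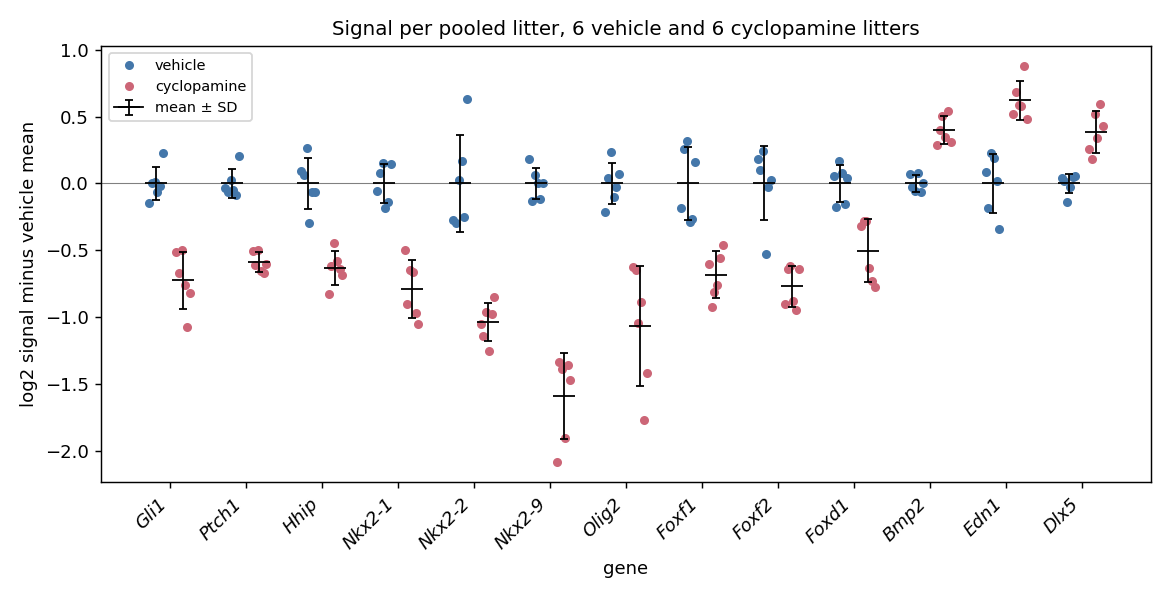
Log2 signal of 13 genes in each pooled litter, drawn as the difference from the vehicle mean of that gene (vertical axis, log2 units; horizontal axis, gene), with blue points for vehicle, red points for cyclopamine and black bars for mean ± SD of 6 litters. The 10 genes from Gli1 to Foxd1 lie lower in cyclopamine litters, by -0.50 to -1.59 on average, and Bmp2, Edn1 and Dlx5 lie higher, by 0.40, 0.62 and 0.39.

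Across all genes, 49 passed an adjusted p of 0.05, of which 22 rose and 27 fell, or 55.1% lower against 43.0% without cyclopamine litter 1. At 1.5-fold or more, 17 passed, of which 2 rose and 15 fell. Reductions therefore reached larger sizes, up to 3.01-fold against 1.56-fold for increases, and the median absolute change of the 49 genes was 0.42 on the log2 scale. In 45 of the 49 genes the 6 cyclopamine litters did not overlap the 6 vehicle litters. Over all genes this held for 138, or 0.622%, where chance gives 0.216%. At an unadjusted p of 0.05 there were 1589 genes, 926 higher and 663 lower, where chance gives 1109 on average. Several other splits of the arrays gave more, up to 2781, so this excess does not by itself set the treatment apart from chance. When 1 litter was left out, all 49 genes kept their direction, which is fixed beforehand for the 45 whose groups do not overlap. The count of 49 changed. It was 27, 32, 28, 39, 28 and 33 without vehicle litters 1 to 6 in turn, and 79, 32, 19, 25, 22 and 29 without cyclopamine litters 1 to 6 in turn. Except without cyclopamine litter 1 it fell, and each of these fits also had fewer arrays. Of the 49 calls, 17 held in all 12 fits without 1 litter, 7 were lost in 1 to 5 of them and 25 in 6 or more. With array cluster as a block the count was 55, and 44 of these were among the 49.

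Other genes among the largest decreases were Dbx1, a homeobox gene of neural progenitors, at -0.96 (SE 0.17, adjusted p = 0.0280), and the nuclear receptor Nr0b1 at -0.85 (SE 0.14, adjusted p = 0.0158). The pseudogene entry Sfta3-ps was at -0.80 (SE 0.12, adjusted p = 0.00875), and Pappa, a protease that cleaves insulin-like growth factor binding proteins, was at -0.63 (SE 0.08, adjusted p = 0.00333). Fgf15, a fibroblast growth factor of the neural tube, fell by 0.36 on the log2 scale (SE 0.06, adjusted p = 0.0279), and its other, dimmer row was at -0.08. The calls of Dbx1 and Fgf15 were each lost in 6 of 12 fits without 1 litter, and that of Nr0b1 in 1. Fgf15 was the 1 gene past the test among 21 fibroblast growth factor ligands, receptors and feedback genes, whose mean was -0.02 (95% interval -0.08 to 0.04), and adjusted over the list alone 3 fell and 0 rose. Fgf8 was at -0.01 (adjusted p = 0.983).

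The largest increases were those of a cadherin and of a secreted signalling peptide. Cdh19, a cadherin of neural crest derivatives, rose 1.56-fold, from 5.67 ± 0.14 to 6.31 ± 0.17, and Edn1, the ligand endothelin 1, which patterns the pharyngeal arches, rose 1.54-fold, from 6.82 ± 0.22 to 7.44 ± 0.14 (log2, n = 6 each). Bmp2, a bone morphogenetic protein, rose 1.32-fold, and Dlx5, a distal-less homeobox gene, rose 1.31-fold. Adjusted p values were 0.00727 for Cdh19, 0.0116 for Edn1, 0.0109 for Bmp2 and 0.0140 for Dlx5. Log2 increases of the other 8 genes among the 12 largest were 0.47 for Rpp25, a subunit of ribonuclease P, 0.46 for Smtnl2, 0.42 for the glucose transporter gene Slc2a3, 0.41 for Tmem108, 0.36 for Dmrt3, 0.36 for the synaptotagmin gene Syt3, 0.36 for Sgpp2 and 0.35 for Phlda1, with adjusted p from 0.00875 for Dmrt3 to 0.0490 for Sgpp2. Values of Sgpp2 overlapped between the groups, and the dimmer row of Tmem108 was at -0.09, opposite to the row tested. Calls were lost in 10 of 12 fits without 1 litter for Sgpp2 and Syt3, 9 for Smtnl2, 8 for Tmem108, 5 for Phlda1, 2 for Slc2a3 and 1 each for Rpp25 and Dlx5.

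Of the lists around these rising genes, the bone morphogenetic protein, first-arch and both Wnt lists did not pass as wholes in the main fit. The placode list, which also holds Dlx5, passed and is described below. When 1 litter at a time was left out, camera at the preset correlation called the bone morphogenetic protein list in 4 of 12 fits (lowest adjusted p = 0.0282). It called the canonical Wnt targets in 3 (0.0184), the Wnt ligand and Frizzled list in 1 (0.0444) and the first-arch list in 0. In the bone morphogenetic protein pathway 1 of 20 genes rose, Bmp2, and the list mean was 0.04 (95% interval -0.01 to 0.08, camera adjusted p = 0.0668), with 2 higher and 1 lower adjusted over the list alone. Among 15 genes of the first-arch mesenchyme list 2 rose, Edn1 and Dlx5, and adjusted over the list alone 4 rose and 2 fell. Its mean was 0.08 (95% interval -0.01 to 0.16, camera adjusted p = 0.154), and Dlx6, the genomic neighbour of Dlx5, was at 0.39 (adjusted p = 0.0809). Of 26 Wnt ligand, Frizzled and secreted Frizzled-related genes only Fzd7 passed, at 0.20 (SE 0.04, adjusted p = 0.0405, lost in 10 of 12 fits without 1 litter), with a list mean of 0.03 (95% interval -0.02 to 0.08), and adjusted over the list alone 2 rose and 0 fell. In 14 canonical Wnt target genes 0 passed, also adjusted over the list alone, with Axin2 at 0.08 (adjusted p = 0.753), Rnf43 at 0.21 (adjusted p = 0.359), Sp5 at 0.14 (adjusted p = 0.733) and a mean of 0.05 (95% interval -0.01 to 0.10).

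Genes of placodes, surface ectoderm and migrating crest were higher by small amounts. Of 14 olfactory and lens placode genes 1 rose, Dlx5, and 5 rose adjusted over the list alone, with Sp8 at 0.27 (adjusted p = 0.140), Pax6 at 0.15 (adjusted p = 0.139) and Fgf8 at -0.01. In this list 6 genes also stand in another list. Dlx5, at 0.39, and its neighbour Dlx6, higher by a like amount, are both first-arch members too. The placode list was not tested without them. The list mean was 0.13 (95% interval 0.09 to 0.18, camera adjusted p = 2.39e-07, adjusted p = 0.00512 with an estimated correlation). Of 19 surface ectoderm genes 0 passed over all genes and 5 rose adjusted over the list alone, with the protease inhibitor gene Spint1 at 0.32 (adjusted p = 0.176), the epidermal factor Grhl3 at 0.27 (adjusted p = 0.240) and the pan-epithelial gene Epcam at -0.04. That list had a mean of 0.10 (95% interval 0.05 to 0.15, camera adjusted p = 8.61e-06, adjusted p = 0.0297 with an estimated correlation). Of 8 migratory crest and glial genes 0 passed over all genes and 3 rose adjusted over the list alone, with Sox10 at 0.48 (adjusted p = 0.139) and Erbb3 at 0.28 (adjusted p = 0.116). Their mean was 0.14 (95% interval 0.08 to 0.20, camera adjusted p = 0.000260, adjusted p = 0.0291 with an estimated correlation). Endothelial genes, as markers of another cell type, had a mean of 0.03 (95% interval -0.02 to 0.08), with Sox18 at 0.30 (adjusted p = 0.112), Flt1 at 0.17 (adjusted p = 0.574) and 1 gene higher adjusted over the list alone.

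The list of hypoxia and glycolysis genes passed as higher at the preset correlation without any single member passing over all genes. Of 17 genes 8 rose adjusted over the list alone, with Ddit4 at 0.55 (SE 0.22, adjusted p = 0.553), Bnip3 at 0.45 (SE 0.13, adjusted p = 0.282), the glucose transporter gene Slc2a1 at 0.22 (adjusted p = 0.0659) and Gapdh at 0.02. The mean was 0.22 (95% interval 0.01 to 0.44) and camera gave adjusted p = 9.32e-11, but the call was lost with adjusted p = 0.119 with an estimated correlation, and the exact permutation test gave adjusted p = 0.120. Relative to the mean of all litters, cyclopamine litters 5 and 6 lay at 0.28 and 0.43, and the other 4 cyclopamine litters at -0.05 to 0.04, within the vehicle range of -0.24 to 0.05.

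Lists of neuronal, neuroepithelial and oral ectoderm genes passed as lower at the preset correlation, and all 3 calls were lost with an estimated correlation. Of 20 neuronal differentiation genes 0 passed over all genes and 7 fell adjusted over the list alone, with the proneural factor Neurod4 at -0.64 (SE 0.16, adjusted p = 0.158) and Nhlh1 at -0.53 (SE 0.16, adjusted p = 0.312). The list mean was -0.17 (95% interval -0.31 to -0.04, camera adjusted p = 1.78e-07, adjusted p = 0.0978 with an estimated correlation), and it did not pass the exact permutation test (adjusted p = 0.0623). Of 18 forebrain neuroepithelium genes 0 passed and 4 fell, with 1 higher, adjusted over the list alone. Fabp7, a radial glial fatty acid binding protein, was at -0.41 (SE 0.09, adjusted p = 0.0878), Hesx1 at -0.38 (adjusted p = 0.427), Sox2 at -0.01 and Otx2 at 0.01. The mean of that list was -0.09 (95% interval -0.14 to -0.03, camera adjusted p = 0.00856, adjusted p = 0.222 with an estimated correlation, exact permutation adjusted p = 0.0139). Of 9 oral ectoderm and pituitary genes 1 fell, Foxe1, a forkhead factor of the thyroid and palate, at -0.42 (SE 0.07, adjusted p = 0.0158; lost in 1 of 12 fits without 1 litter), and its other row was at -0.73. With 4 lower and 0 higher adjusted over the list alone, the mean was -0.15 (95% interval -0.23 to -0.07, camera adjusted p = 0.000423, adjusted p = 0.0978 with an estimated correlation, exact permutation adjusted p = 0.0173).

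Lists of proliferation, stress and damage genes did not pass camera, although other tests called the immediate early genes. The 24 G1/S genes had a mean of -0.01 (95% interval -0.05 to 0.03), with Myc at 0.23 (adjusted p = 0.132) and Cdk6 at -0.22 (adjusted p = 0.471), and the 21 G2/M genes had a mean of 0.00 (95% interval -0.04 to 0.04), with Bub1 at -0.09 and Nusap1 at -0.05. The 19 p53 target genes had a mean of 0.00 (95% interval -0.07 to 0.07), with Btg2 at -0.19 and Ccng1 at -0.15, and the 10 heat shock genes a mean of 0.02 (95% interval -0.18 to 0.22), with Hsph1 at -0.13 and Hspa1a at 0.15. Without cyclopamine litter 5 the heat shock mean was -0.06 and Hspa1a was at -0.18. The 17 immediate early genes had a mean of 0.05 (95% interval 0.02 to 0.09, camera adjusted p = 0.0836, exact permutation adjusted p = 0.0462, fry adjusted p = 0.0186 by direction), with Ier3 at 0.28 (adjusted p = 0.871), or 0.09 without cyclopamine litter 6 and 0.42 without vehicle litter 4. In these 5 lists 0 members passed over all genes, and adjusted over the list alone 1 of the G1/S genes rose and 0 others changed.

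Of 18 genes tied to orofacial clefts 2 fell, Foxf2 and Foxe1, while 5 rose and 2 fell adjusted over the list alone, with Bmp4 at 0.23 (adjusted p = 0.432) and Grhl3 at 0.27. The list median was 0.02 and its mean -0.03 (95% interval -0.09 to 0.03, camera adjusted p = 0.764), opposite in sign. With 1 higher and 1 lower adjusted over the list alone, the 15 retinoic acid genes had a median of 0.04 and a mean of -0.00 (95% interval -0.06 to 0.06, camera adjusted p = 0.182), with Aldh1a1, which makes retinoic acid, at -0.50 (SE 0.12, adjusted p = 0.152) and Cyp26c1, which degrades it, at -0.19. The 19 cholesterol synthesis genes, a pathway of interest because cyclopamine is a steroidal compound, passed camera at adjusted p = 0.0451 with a mean of 0.04 (95% interval -0.05 to 0.13), 0 members past the test, also adjusted over the list alone, and Tm7sf2 at 0.12 and Insig1 at 0.10. That call was lost with adjusted p = 0.530 with an estimated correlation, and with adjusted p = 0.224 with array cluster as a block. It was also lost without vehicle litters 1 and 4 (adjusted p = 0.0938 and 0.434) and without cyclopamine litters 2, 3, 4 and 6 (adjusted p = 0.112, 0.0889, 0.238 and 0.0695).

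**Figure D2:**
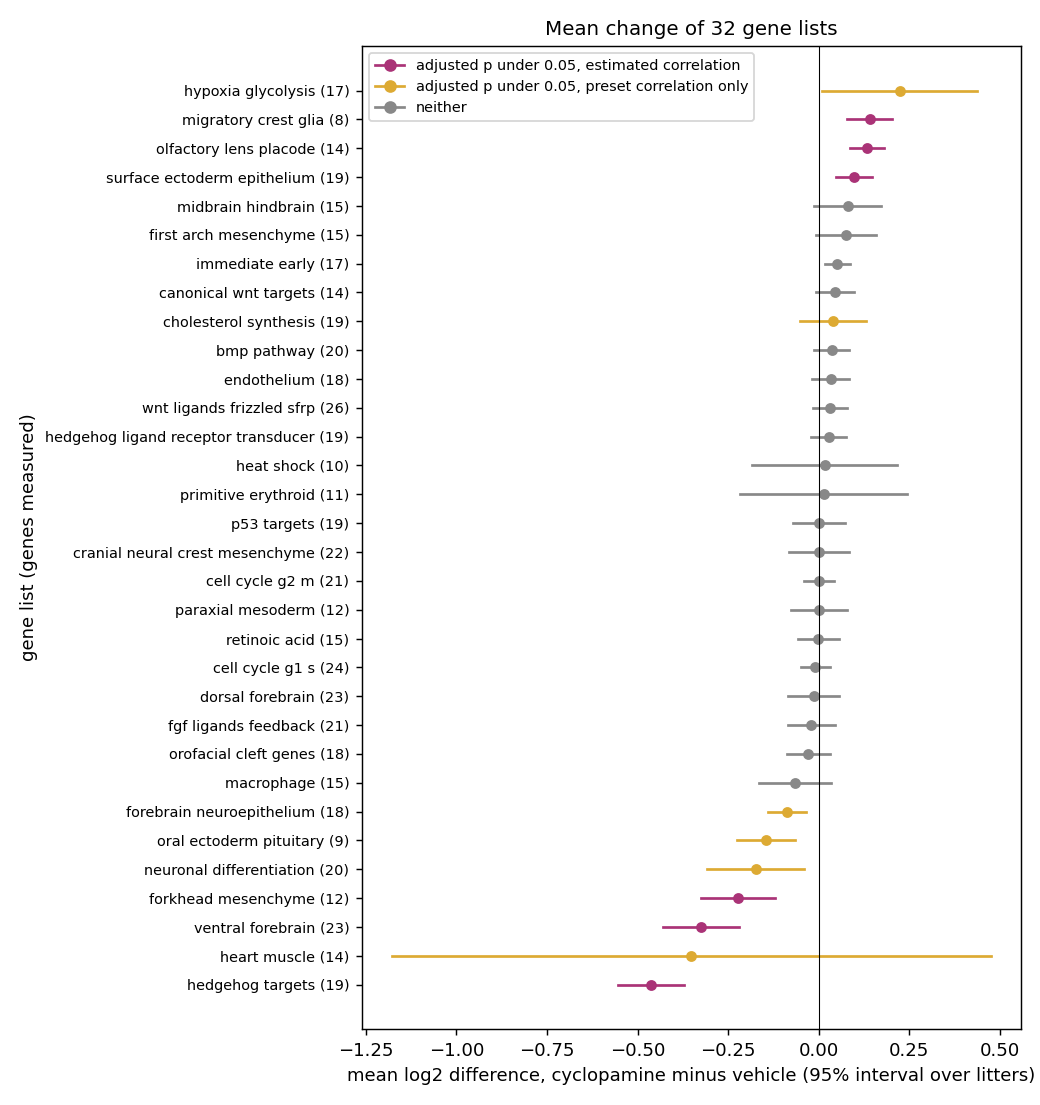
Mean log2 difference, cyclopamine minus vehicle, of the 32 gene lists tested (horizontal axis, log2 units; vertical axis, list with the number of genes measured), with lines for the 95% interval over 12 litters and colour for the camera test. Hedgehog targets lie lowest at -0.46 and 6 lists pass with an estimated correlation, 3 lower and 3 higher; the wide line of the heart muscle list, from -1.18 to 0.47, is set by vehicle litter 1, without which the mean is 0.02.

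Markers of other tissues differed between single litters more than between the groups. Heart muscle genes were far higher in vehicle litter 1 than in any other: Myl7, an atrial myosin light chain, was at 10.30 there against a median of 6.31 in the other 11 arrays, and Actc1, cardiac actin, at 10.54 against 6.21. Through this litter the 14 heart genes had a mean difference of -0.35 between the groups (95% interval -1.18 to 0.47, camera adjusted p = 0.000328, adjusted p = 0.434 with an estimated correlation), with 0 members past the test. Without vehicle litter 1 the mean difference was 0.02 and the list no longer passed (adjusted p = 0.856). The 15 macrophage genes had a mean of -0.06 (95% interval -0.16 to 0.03, camera adjusted p = 0.0546), with Fcer1g at -0.25 and Cx3cr1 at -0.15. Without 1 litter that list passed camera in 5 of 12 fits, and its mean was -0.03 without vehicle litter 2. The 11 primitive erythroid genes had a mean of 0.01 (95% interval -0.22 to 0.24, or -0.05 without vehicle litter 4), with Nfe2 at 0.08 and Hemgn at -0.08. The 15 midbrain and hindbrain genes had a mean of 0.08 (95% interval -0.01 to 0.17, camera adjusted p just over the threshold, exact permutation adjusted p = 0.203), with Pax8 at 0.29 and Hoxb2 at 0.27, and the 12 paraxial mesoderm genes a mean of 0.00 (95% interval -0.08 to 0.08), with Tbx18 at -0.42 and Meox1 at 0.35, or 0.12 without cyclopamine litter 4. Of these 4 lists, adjusted over the list alone, 1 gene rose and 1 fell among the paraxial mesoderm genes and 0 changed in the others.

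Litters also differed in transcripts of the sex chromosomes. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty was 4.58 in vehicle litter 1 and 7.39 to 9.25 in the other litters, and Xist, transcribed from the inactive X chromosome, was at 9.04 in cyclopamine litter 1, 11.43 in vehicle litter 6 and 12.05 to 12.94 elsewhere. Between the groups Uty differed by 1.01 (SE 0.52, adjusted p = 0.743) and Kdm5d by 0.94 (SE 0.63, adjusted p = 0.844), or by 0.48 and 0.25 without vehicle litter 1. With the Y-linked score as a covariate 29 genes passed, 27 of them among the 49. Because vehicle litter 1 lies far from the rest on this score, the covariate in part marks that litter. Without that litter 27 genes passed.

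**Figure D3:**
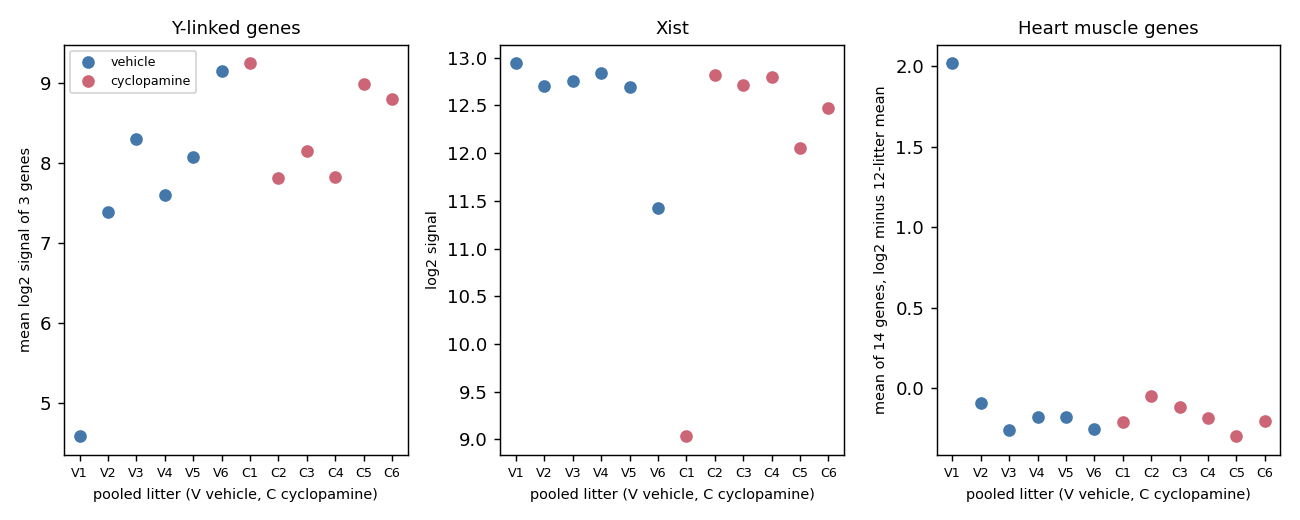
Mean log2 signal of 3 Y-linked genes, log2 signal of Xist, and mean log2 signal of 14 heart muscle genes relative to the mean of all 12 litters (vertical axes), for each pooled litter (horizontal axis; V, vehicle, blue; C, cyclopamine, red). Vehicle litter 1 stands apart in the Y-linked score, at 4.58, and in the heart muscle genes, and cyclopamine litter 1 has the lowest Xist, at 9.04.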

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

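Every named gene was checked in each group of 6 litters for a highest or lowest litter far from the other 5, by the gap to its neighbour over the range of the group, against Dixon's 95% critical value for 6 samples. Of 154 groups 20 passed this limit, where chance passes about 1 in 20, or 7.70. The excess is not a test, because the naming rule favours large differences, which a single litter can create. Genes on the same arrays are also not independent. The tests of the heart muscle pattern were chosen after the result was seen.

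Heart muscle genes stood apart in vehicle litter 1, where Myl7 was at 10.30 (gap over range 0.893) and Actc1 at 10.54 (0.869). All 14 heart genes measured had their highest value of the 12 arrays in that litter, among them Tnnt2 at 10.28 against a median of 6.77 in the other 11 arrays and Nppa at 10.09 against 6.57, which is consistent with heart tissue in that pool, since the heart lies close to the face at this stage. A shift of the array as a whole is argued against: the median rise of the 14 genes was 2.16 on the log2 scale, or 4.45-fold, against at most 0.21 in 10000 random lists of matched level. Of the 14 genes 0 stand in another list, and how many of them the dissected tissue itself expresses was not tested. A difference in the boundary of the dissection and a biological difference of that litter were not tested and stay open.

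The same litter had the lowest Kdm5d, a Y-linked gene, at 4.14 against a vehicle median of 8.00 (gap over range 0.638), and the lowest vehicle value of Smo, 11.30 against a median of 11.44 (0.675).

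Of genes that fell after cyclopamine, several had a single litter apart in 1 group. Foxf2 was at 7.15 in vehicle litter 4, the vehicle litter nearest to the cyclopamine level, against a vehicle median of 7.74 (gap over range 0.650). Nr0b1 was at 7.44 in vehicle litter 3 against a median of 6.80 (0.697). Dbx1 was at 8.04 in cyclopamine litter 6 against a cyclopamine median of 8.92 (0.627). In cyclopamine litter 5, Fgf15 was at 9.62 against 9.83 (0.681) and Foxe1 at 6.90 against 7.18 (0.659).

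Within its group, cyclopamine litter 5 also held the lowest Cdk6, 9.23 against a median of 9.59 (gap over range 0.683), the lowest Hoxb2, 4.92 against 5.23 (0.651), and the highest Hspa1a, an inducible heat shock gene, 8.02 against 6.17 (0.826). The early stress gene Ier3 was highest of its group in vehicle litter 4 at 8.47 against 7.61 (0.709) and in cyclopamine litter 6 at 8.94 against 7.84 (0.715). Meox1, a somite gene, was at 8.37 in cyclopamine litter 4 against 7.06 (0.693).

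Single litters also stood apart for Hemgn at 6.45 in vehicle litter 4 against 6.96 (0.718), Foxd2 at 8.73 in vehicle litter 6 against 8.52 (0.626), Tm7sf2 at 8.16 in vehicle litter 6 against 8.40 (0.637), Nusap1 at 11.13 in vehicle litter 3 against 10.97 (0.639) and Syt3 at 8.11 in cyclopamine litter 6 against 7.83 (0.629).

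Rows with no gene named here were outside the comparisons by gene. When every row was tested, 3 of them passed, 1 higher and 2 lower. Row 17202283 was higher after cyclopamine by 0.77 on the log2 scale (SE 0.10, limma adjusted p = 0.0278), at 8.63 ± 0.24 against 7.87 ± 0.14 in vehicle litters. The lower rows were 17281304 at -1.09 (SE 0.13, adjusted p = 0.00918) and 17417622 at -0.67 (SE 0.06, adjusted p = 0.000395).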

How the results depend on the processing

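All 49 genes past the main test kept their direction under every alternative fitted to single genes. This carries little weight: in 45 of them the groups did not overlap, so leaving out litters could not turn the direction. How many genes passed varied widely, and among the 12 lists that passed, the heart muscle list was the 1 that reversed. Cluster, Y-linked, both-litters-1 and list permutation settings were chosen after seeing the data. Against 49 genes, 17 at 1.5-fold and 29 of the 77 named genes, testing every row gave 11, 11 and 8, with 41345 rows in place of 22180 genes and another variance moderation, which were not separated. The fit without an intensity trend gave 18, 14 and 15, and the unmoderated fit 2, 2 and 2, with 1563 genes at an unadjusted p of 0.05. The larger array cluster alone (7 arrays) gave 12, 8 and 10, and the smaller alone (5 arrays) 2, 1 and 2, with fewer arrays in each fit. The Y-linked score as a covariate gave 29, 16 and 21, and an adjusted p of 0.01 left 12 genes. The cause was tested for none of these. Leaving out 1 litter at a time gave 19 (without cyclopamine litter 3) to 79 (without cyclopamine litter 1) genes, 13 to 20 at 1.5-fold, 16 to 35 named genes and 11 to 17 lists. Of the 48 named genes not past the test, 4 turned direction in at least 1 of these fits and 15 others moved by over 1.5 times. Quantile normalization gave 41 genes and shared 35 with the 49. The share of lower genes, 55.1% in the main setting, was 65.9% there and 77.8% without a trend, but under 50% with array weights (48.4% of 64), without both litters numbered 1 (44.6% of 56) and without cyclopamine litter 1 (43.0%).

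Of all 32 lists tested 12 passed in the main setting, 6 with an estimated correlation, 8 with fry by direction, 21 with fry in either direction and 9 with the exact permutation test. Of the 12 themselves, 6, 7, 10 and 8 passed these tests. The heart muscle list changed direction without vehicle litter 1 (adjusted p = 0.856), without both litters numbered 1 (0.847), with the Y-linked covariate (0.204) and in the larger cluster alone (0.0384). Each of these fits leaves out vehicle litter 1 or, for the covariate, gives it a score far from the others. Over its alternatives adjusted p ran from 1.02e-06 to 0.856, with 1.38e-05 (without vehicle litter 6) the lowest when 1 litter was left out. Cholesterol synthesis ran from 0.000877 to 0.807. Hedgehog targets and ventral forebrain passed under every alternative run, with adjusted p of at most 0.0139, and surface ectoderm under all but the smaller cluster alone (0.150). Without 1 litter the mean of 9 of the 20 lists that did not pass also turned sign. Over all single genes and lists, 247 comparisons lost a call, 57 gained one, 4 reversed the direction of a called result and 2697 did none of these.

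Replicate numbers did not pair the litters: residuals of same-numbered litters correlated at -0.24 to 0.23, above 0.1 in 3 of 6 pairs, and 2 of 6 matched their own number best. With the replicate number as a block 41 genes passed, 31 of them among the 49. Leaving out the dimmest rows cut the genes tested from 22180 to 16139, and 60 passed, among them all 49; dim signal, the number of tests and the moderation were not separated.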

Other observations

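The tests of the ventral forebrain and surface epithelium patterns were chosen after the results were seen; those on other splits of the arrays were set before.

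Genes past the test that the report does not describe, named here after their values were seen, were 20 in number. Transcription factors of the nervous system were among the lower ones: Pou3f2 was at -0.49 (SE 0.09, adjusted p = 0.0280), Pou3f4 at -0.59 (SE 0.09, adjusted p = 0.0109) and Onecut1 at -0.37 (SE 0.07, adjusted p = 0.0431), with the neuronal splicing regulator Srrm4 at -0.40 (SE 0.07, adjusted p = 0.0280). Apela, a peptide ligand of the apelin receptor, was at -0.60 (SE 0.09, adjusted p = 0.0114), the chemokine receptor gene Ackr3 at -0.35 (SE 0.07, adjusted p = 0.0464) and the growth arrest gene Gadd45g at -0.42 (SE 0.08, adjusted p = 0.0480). Clstn2 at -0.52, Dleu7 at -0.53, Zfp9 at -0.35 and Heg1 at -0.18 were also lower.

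Among those that rose were Porcn, which acylates Wnt ligands for secretion, at 0.27 (SE 0.05, adjusted p = 0.0490), and the Wnt receptor gene Ror2 at 0.26 (SE 0.05, adjusted p = 0.0464), beside the receptor Fzd7. Shisa2, which retains Frizzled and fibroblast growth factor receptors in the endoplasmic reticulum, was at 0.26 (SE 0.05, adjusted p = 0.0396). The epithelial genes Rab25 at 0.31 and Mapk13 at 0.32, the adhesion gene Cadm1 at 0.18, the reelin adaptor Dab1 at 0.28, Rtn4rl2 at 0.34 and the amino acid transporter gene Slc38a4 at 0.23 were also higher. Values of Porcn, Ror2 and Slc38a4 overlapped between the groups. When 1 litter at a time was left out, the calls of Pou3f4, Apela and Zfp9 held in all 12 fits, and each of the other 17 was lost in 7 to 11. No enrichment was tested for these genes, so they name no theme.

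Ventral forebrain genes were lower by -0.33 on average, and a smaller share of forebrain tissue in the dissected pieces could lower them too. The 22 ventral genes not shared with the neuroepithelium list fell further than 17 pan-neuroepithelial genes, -0.34 against -0.10. The difference was -0.25 (95% interval -0.32 to -0.18, exact permutation p = 0.00216, the smallest possible). Part of the ventral fall came from Hedgehog targets: the 19 ventral genes outside that list had a mean of -0.19. An even loss of forebrain would lower genes also expressed elsewhere by less, and how restricted either set is was not tested. The comparison therefore does not decide on an even loss. The comparison cannot tell whether the dissection took less of the ventral part alone. It is also blurred by genes such as Pax6, which stands in the placode list that rose. With array cluster as a block the difference of the ventral genes was -0.34 (95% interval -0.44 to -0.24). The clusters were set after group means were removed and hold vehicle and cyclopamine litters in similar numbers. Blocking on them could therefore hardly change the difference, and this fit does not decide whether array structure adds to the fall. With the Y-linked score as a covariate the difference was -0.32 (95% interval -0.45 to -0.20). The sex of the embryos, as far as this score measures it, therefore does not carry the fall of the ventral genes. A smaller share of forebrain tissue stays open. Other explanations left open are untested here. Among them is that inhibition of the Hedgehog signal lowered these genes, per cell or through a smaller ventral share of the forebrain. A delay in development and an effect of the drug outside the pathway are others.

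Surface ectoderm genes were higher by 0.10 on average, and a larger share of surface ectoderm in the pieces may account for it. In a further test, 19 general epithelial genes outside all fixed lists were higher by 0.0894 on average (95% interval 0.04 to 0.14, exact permutation p = 0.00433), though unequally, with Prss8 at 0.18, Krt19 at 0.18, Dsp at 0.01 and Krt7 at -0.08. These genes were written down before their values were looked at, in place of an earlier set that overlapped the surface ectoderm list and was also higher. Their rise is therefore not an independent check. A smaller share of mesenchyme and neuroepithelium would raise every other cell type alike, and the surface ectoderm list exceeded endothelial and erythroid genes by 0.0731 (95% interval -0.01 to 0.16, exact permutation p = 0.0887), which leaves it open. Of the surface ectoderm genes 4 stand in another list. A higher expression per epithelial cell after cyclopamine was not tested and stays open.

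Counts of called genes and lists as high as the real ones came from 3 in 100 splits in each case. That share is below the limit set beforehand, which makes a chance division of the litters unlikely but does not exclude it. Of 100 splits of the 12 arrays into 6 and 6, the real one included, 3 gave as many genes (49 in the real split, 307 in the highest other) and 3 as many at 1.5-fold (17 against 150). The high ones follow a structure of the samples: the split with 307 sets the 5 arrays of the smaller cluster and vehicle litter 6 against the rest. With cluster as a block the treatment count was 55. Of the 99 other splits 5 called any gene. For lists, 3 of 100 splits gave as many as the 12 of the real one, and 13 was the highest other. The other splits called 5 lists in the median, so a list call at the preset correlation alone carries little weight.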
